A study of Mus musculus with 3 samples.

How the data were processed

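PARP-1 ChIP-seq libraries were made by the submitters from mouse nucleus accumbens. Per the labels, punches from 10 mice were pooled per replicate, chromatin was precipitated with the polyclonal antibody ab6079, fragments of 250 to 350 bp were selected and amplified with 21 PCR cycles, and reads of 100 bp were sequenced. The submitters' processing notes name the mm9 genome build and CASAVA 1.8.2. The aligner, the handling of duplicate reads, the window settings and the threshold for listing a site were not given in the sources used here. All coordinates are those of the deposited table, in mm9.

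The deposited table lists 1727 sites from the authors' comparison of cocaine with saline, and its name gives the program diffReps and a negative binomial test. Its columns are headed treatment and control. Control was taken as saline, because the series design text calls the saline animals control and the table's name sets cocaine against saline. Per the file headers and values, the deposited count columns hold normalized read counts of 2 cocaine and 3 saline replicates, each scaled by the authors with 1 factor per library. The labels state 3 replicates per group, and which cocaine replicates the 2 values belong to is not stated. The replicate numbers used here only give the order in the table. Of the tests below, only limma's p-values take in the spread between these pools of mice. limma draws each site's spread toward a value shared by all 1727 sites, most of them with low counts. At sites of high count its p-values therefore do not measure the spread of those sites alone. Those of the exact conditional test measure counting error only. Fisher's and the permutation tests take sites or genes as their units, so their p-values do not measure variation between pools. Per the file headers, the deposited group averages are a signal, the mean normalized read count of a group. The enrichment columns are a ratio over a background set by the authors. The authors' deposited fold change is on the log2 scale, cocaine over saline, and equals the log2 ratio of the group averages. The deposited p-value and adjusted p-value columns are the authors' own, for each site and for one window of it. The adjusted values imply that 40757 tests were adjusted over, and the largest window p was 9.95e-05.

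Within a library, 100.0% of the 8635 values were whole multiples of 1 value within 0.1 read, so whole reads were recovered. A read was worth 0.822 and 1.14 in the cocaine libraries and 1.06, 0.912 and 1.09 in the saline libraries. Depth limits precision. In the sites where its group was higher, leaving out those with a mean count of 100 or more, a replicate held a median of 14 to 19 reads, and in those where its group was lower 3 to 5. In the former, no replicate held fewer than 12 reads. Intervals cover counting error only, since PCR reads without molecular identifiers are not independent molecules.

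Counts, shares with exact Clopper-Pearson 95% intervals and medians were taken over the authors' sites, with no threshold added. Features and chromosomes were compared between higher and lower sites with Fisher's exact test and Benjamini-Hochberg adjustment. Distances to the transcription start were compared with a two-sided permutation test of medians with 100000 resamples, and neighbouring directions with 10000 permutations within chromosomes. The 14 gene lists, the rule for named genes, the tests on the authors' sites and the first group of alternatives below were fixed before the data were examined. The rule took, per direction and with 1 site per gene in gene body or promoter, the 6 genes with the smallest authors' adjusted p and the 6 with the largest log2 fold change at an adjusted p under 0.05. It added the 3 genes with the most sites per direction, up to 4 genes per list by smallest adjusted p, and Sdk1 and Parp1 whatever their values. Because values per replicate were found, limma 3.58.1 (R 4.3.3) was run on log2(value + 1) with Benjamini-Hochberg adjustment over the 1727 sites. An exact two-sided binomial test compared the cocaine share of a site's reads with the cocaine share of depth, 41.5%. That share was taken from the authors' scaling factors, so an error in them would carry into the test. Both tests were added after seeing the data. They cover only sites already selected on the same libraries, so their counts do not estimate how many sites differ in the genome. Fold changes on the log2(value + 1) scale understate changes at low counts. Selection on the same libraries can overstate the fold changes of listed sites, and no correction for it was made.

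Both tests were checked on simulated Poisson reads for the 1727 sites, with 100 sites changed 2-fold and 100 changed 4-fold. limma called 9 and 91 of these and 2 of 1527 unchanged sites. The exact test called 53 and 100 of them and 5 of the unchanged sites. Both were counted at a Benjamini-Hochberg adjusted p under 0.05. The limit of p under 1e-04 used for the exact test below was not checked in this way. The unchanged level of a simulated site was its mean over the 5 libraries, which lies above the saline mean at higher sites. The simulation held no spread between pools beyond counting error and no selection of sites. Its counts therefore do not give the power or the false calls for the listed sites. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used.

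Alternatives were stricter adjusted p (0.01 and 0.001), an absolute log2 fold change of at least 1, a mean count of at least 10 in the higher group, merging of sites closer than 1 kb, autosomes only, promoter classes merged, neighbours within 10 kb and 1 Mb, and genes with both directions counted by their best site. Added after seeing the data were leaving out sites with a mean count of 100 or more, pseudocounts of 0.5 and 5, and leaving out each replicate. Gene names were taken from the table, and 687 of the 688 genes with a site matched the RefSeq table of GRCm38.p6 by symbol, synonym or accession. That build differs from mm9, so none of its coordinates or lengths was used; its protein-coding symbols gave the list sizes. The planned comparison of lists with length-matched genes of the genome was therefore not run. The authors' annotation does not separate exons from introns. Gene lengths are from the coordinates in the deposited table.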

Results

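PARP-1 is a nuclear enzyme that attaches chains of ADP-ribose to itself, to histones and to other chromatin proteins. Its occupancy of the genome was measured by ChIP-seq, in which fragments of cross-linked chromatin bound by an antibody are sequenced, in the nucleus accumbens of C57BL/6 mice. The nucleus accumbens is the part of the ventral striatum on which drugs of abuse act most directly. Mice received cocaine at 20 mg/kg or saline once a day for 7 days and were killed 30 min after the last injection. Each ChIP replicate pooled tissue from 10 mice, and the labels state 3 replicates per group. The table of differential sites analysed here carried values of 2 cocaine and 3 saline replicates, so n = 2 and n = 3 throughout. It listed 1727 sites from the authors' test of cocaine against saline and no others. In the authors' deposited table, of these sites, 1709 had an adjusted p under 0.05 and 18 did not, of which 17 had a mean count of 100 or more. A DNA input sample of the series had no column of its own in it. Over the listed sites the replicates held 82360 and 61292 reads after cocaine and 47757, 55084 and 46406 reads after saline. The total depth of the libraries was not given in the sources used here. Taking the authors' scaling factors, read from the value of 1 read in each library, as a measure of depth, the shallowest had 72.3% of the deepest.

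The comparison asked where PARP-1 occupancy differed after repeated cocaine. PARP-1 signal was higher after cocaine at 1605 of the 1727 listed sites and lower at 122. The share of higher sites was 92.9% (exact Clopper-Pearson 95% interval 91.6 to 94.1%, which covers the counting of sites only). Of the higher sites, 857 lay outside genes and promoters and 748 in or near genes. The lists of adhesion, voltage-gated channel, glutamate receptor and cAMP, calcium and kinase signalling genes together took 70 of the 1605 higher sites (4.36%). Whether any list held more sites than other genes of the genome was not tested. In the authors' deposited table the median log2 fold change was 1.84 at the higher sites and -1.93 at the lower sites, or 3.58-fold higher and 3.81-fold lower. Among sites with an authors' adjusted p under 0.001, these medians were 2.05 and -0.29. A typical higher site held a median of 15.9 normalized reads after cocaine and 4.46 after saline, and a typical lower site 4.45 and 17.3. Of the 1727 sites, 69 had a mean count of 100 or more, a limit chosen after the values were seen. At these sites changes were small, with a median log2 fold change of 0.04 in the authors' deposited table. They included 38 higher and 31 lower sites. The other 1658 sites comprised 1567 higher and 91 lower sites.

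**Figure D1:**
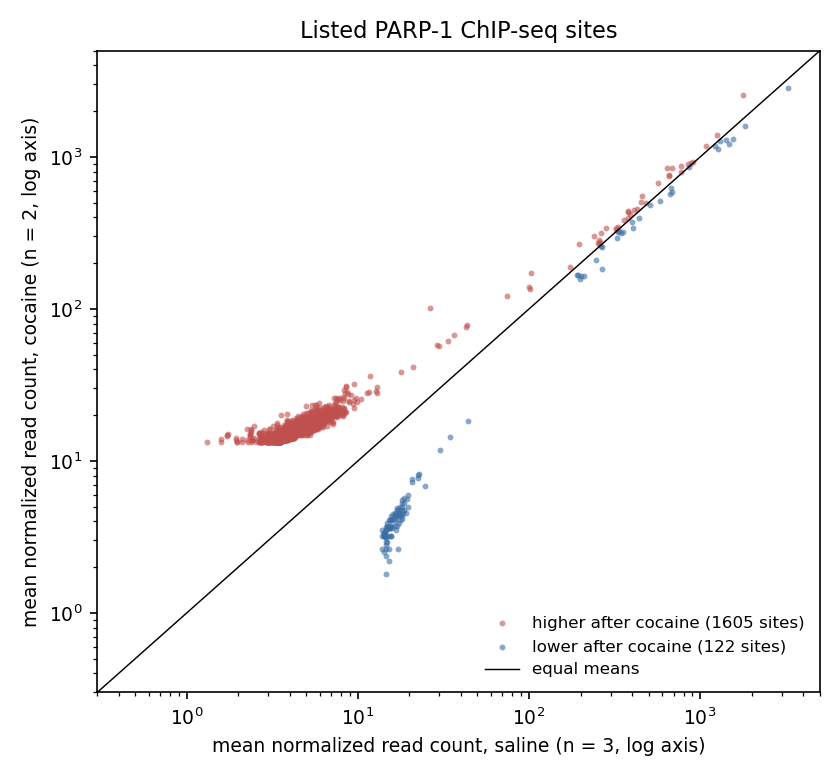
Mean normalized read count per site after saline (x axis, n = 3) and after cocaine (y axis, n = 2), both on log axes, for the 1605 higher and 122 lower sites, with a line of equal means. Most higher sites lie near 15.9 normalized reads after cocaine and 4.46 after saline, and the 69 sites with a mean count of 100 or more lie close to the line.

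At each of the 1658 sites with a mean count under 100, every replicate of the higher group exceeded every replicate of the other group. Groups of 2 and 3 replicates separate in a given direction in 10% of cases by chance, and the sites had been selected on these same libraries. limma's test on log2(value + 1) gave a Benjamini-Hochberg adjusted p under 0.05 at 1649 of the 1727 sites, 1558 higher and 91 lower. An exact conditional test on the recovered reads gave p under 1e-04 at 1355 sites. Neither test is independent evidence, because the sites had been selected on the same libraries, and both tests were chosen after the values were seen. The limma count was 794 without cocaine replicate 1. Without cocaine replicate 2 it was 0 (limma), with 1248 sites at an unadjusted p under 0.05 and 285 at an exact conditional p under 1e-04. Each of these fits had a single cocaine sample, and their smallest adjusted p values were 0.0485 and 0.0561. The median log2 fold change was then 1.87 and 1.799 at the higher sites and -1.86 and -1.77 at the lower sites. The statements of passing sites below rest on limma with all 5 replicates. limma passed 1648 of the 1658 sites with a mean count under 100, so passing was close to fixed for the sites of any list. Where all sites of a list passed, adjustment over the list alone could not fail, so it adds no support.

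Among genes for synaptic and neuronal adhesion molecules, 27 held 34 sites, of which 32 were higher and 2 lower after cocaine, and all 34 passed limma's test, also when adjusted over the list alone. Sdk1, which encodes the immunoglobulin-superfamily adhesion molecule sidekick-1, held 2 higher sites in its gene body on chromosome 5 of mm9. At the first (142251901 to 142253100, 535.0 kb from the transcription start) the normalized read count was 18.5 ± 0.50 (SD, n = 2) after cocaine and 5.71 ± 1.16 (SD, n = 3) after saline. At the second (142272701 to 142273700, 555.7 kb from the start) the counts were 14.0 ± 1.15 and 2.97 ± 1.77. The limma log2 fold changes were 1.56 ± 0.26 (SE) and 2.03 ± 0.46, with adjusted p = 0.00537 and 0.00822. The authors' enrichment over background was 1.57 and 1.14 after cocaine, against a median of 2.62 over the higher sites. After saline it was 0.51 and 0.25, so the second site rose from below background to near it. Nlgn1, the gene of the postsynaptic partner of neurexins neuroligin-1, held 3 higher sites. The one named by the rule rose from 5.57 ± 3.50 to 19.6 ± 3.63 normalized reads (chromosome 3, 25473701 to 25474900). Sites in Cdh13, the gene of a cadherin anchored to the membrane by a lipid, in Csmd3 and in Cdh23, which encodes a cadherin of hair-cell tip links, rose by 2.19 ± 0.58, 2.10 ± 0.25 and 2.11 ± 0.54 on limma's log2 scale (SE). Nrxn3, which encodes a presynaptic neurexin, went the other way. Its site (chromosome 12, 90826801 to 90828100) fell from 18.04 ± 1.62 to 4.48 ± 1.69 normalized reads. Cdh12 held the other lower site of the list and was chosen after its values were seen. Adhesion genes with a site were long, with a median length of 653.1 kb against 70.2 kb for the other genes with a site. The median was 751.8 kb for glutamate receptor and scaffold genes, 280.1 kb for channel genes, 261.4 kb for cAMP, calcium and kinase genes and 229.3 kb for axon guidance genes, against 72.5 to 74.4 kb for the other genes in each case. Long genes can hold more sites by chance, and no length-matched test was run.

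The direction of sites in voltage-gated and related channel genes has to be read against all sites in or near genes, of which 748 of 770 were higher. The same holds for the lists below. The 16 sites in 11 genes were all higher, and all 16 passed, also when adjusted over the list alone. Dpp6, which encodes an auxiliary subunit of A-type potassium channels, held 4 higher sites. The named one rose from 5.36 ± 1.07 to 17.9 ± 2.04 normalized reads (chromosome 5, 27587101 to 27588100). Kcnma1, the gene of the large-conductance calcium-activated potassium channel, rose from 3.02 ± 0.80 to 15.2 ± 0.59 at its named site, and Kcnj6, the gene of a G protein-gated potassium channel, from 6.15 ± 2.32 to 19.8 ± 2.25. The L-type calcium channel gene Cacna1c rose from 3.78 ± 1.36 to 14.6 ± 1.39 (chromosome 6, 118910401 to 118911500, gene body). The site of Cacna2d4, a calcium channel auxiliary subunit gene, lay in the promoter, 0.30 kb downstream of the start, with a log2 fold change of 1.95 ± 0.59 (SE).

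Glutamate receptor and scaffold genes held 6 higher sites in 5 genes and no lower site. All 6 passed, also when adjusted over the list alone. Grm2, which encodes a presynaptic metabotropic receptor, rose from 3.07 ± 0.29 to 13.8 ± 0.23 normalized reads (chromosome 9, 106547001 to 106548000, gene body). The delta receptor gene Grid1, the kainate receptor gene Grik1 and the postsynaptic scaffold gene Dlgap2 rose by 2.02 ± 0.26, 1.53 ± 0.26 and 1.68 ± 0.36 on limma's log2 scale. The list of GABA, glycine and acetylcholine signalling genes held 2 sites, 1 in each direction, and both passed, also when adjusted over the list alone. Chrna5, a nicotinic receptor subunit gene, rose from 3.88 ± 3.16 to 17.0 ± 1.53, and the glycine receptor subunit gene Glra3 fell from 14.2 ± 0.60 to 3.35 ± 0.08. The authors' enrichment of the Chrna5 site was 1.14 after cocaine, near background, and 0.27 after saline.

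Genes of cAMP, calcium and kinase signalling held 16 higher sites in 14 genes, and all 16 passed, also when adjusted over the list alone. Atp2b2, which encodes a plasma membrane calcium pump, was among the 6 genes with the largest increases, from 2.25 ± 2.28 to 16.2 ± 0.37 normalized reads (chromosome 6, 113812801 to 113814000). Dgkg (a diacylglycerol kinase), Akap13 (a kinase anchoring protein) and Plce1 (a phospholipase C) rose by 2.07 ± 0.53, 1.63 ± 0.25 and 1.88 ± 0.39 on the log2 scale. Axon guidance genes held 9 higher sites in 9 genes, all of which passed, also when adjusted over the list alone. The netrin receptor gene Dcc rose from 6.81 ± 1.75 to 21.8 ± 2.93, and the ephrin receptor gene Ephb2 from 2.95 ± 1.75 to 13.4 ± 0.35. Rgmb rose by 1.94 ± 0.37 at a promoter site and Srgap3 by 1.68 ± 0.39 in its gene body on the log2 scale.

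Genes of dopamine signalling and medium spiny neurons, the main neurons of this tissue, held 3 sites in 3 genes, of 50 gene symbols that the list matched by name. All 3 were higher and passed, also when adjusted over the list alone. Rgs9, a regulator of G protein signalling enriched in striatum, rose from 4.09 ± 0.39 to 15.2 ± 0.59. Ptpn5, the gene of a striatum-enriched phosphatase, rose from 4.75 ± 0.50 to 17.1 ± 4.88, and Rasd2, the gene of a striatal small GTPase, from 3.98 ± 1.29 to 14.5 ± 1.96. Among activity-regulated genes 1 site was listed, in Creb1, the gene of a cAMP-responsive transcription factor, and it rose from 4.09 ± 0.39 to 14.6 ± 1.39. Parp1 itself had 0 listed sites. The list of PARP family and chromatin regulators held 13 sites in 8 genes, 11 higher and 2 lower, and all 13 passed, also when adjusted over the list alone. The histone demethylase gene Kdm2b rose by 1.92 ± 0.36 on the log2 scale, Mbd5 by 1.85 ± 0.31 and Auts2, with 3 higher sites, by 1.85 ± 0.37 at the named one. Macrod2, which encodes a hydrolase of mono-ADP-ribose, held 2 higher and 2 lower sites.

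**Figure D2:**
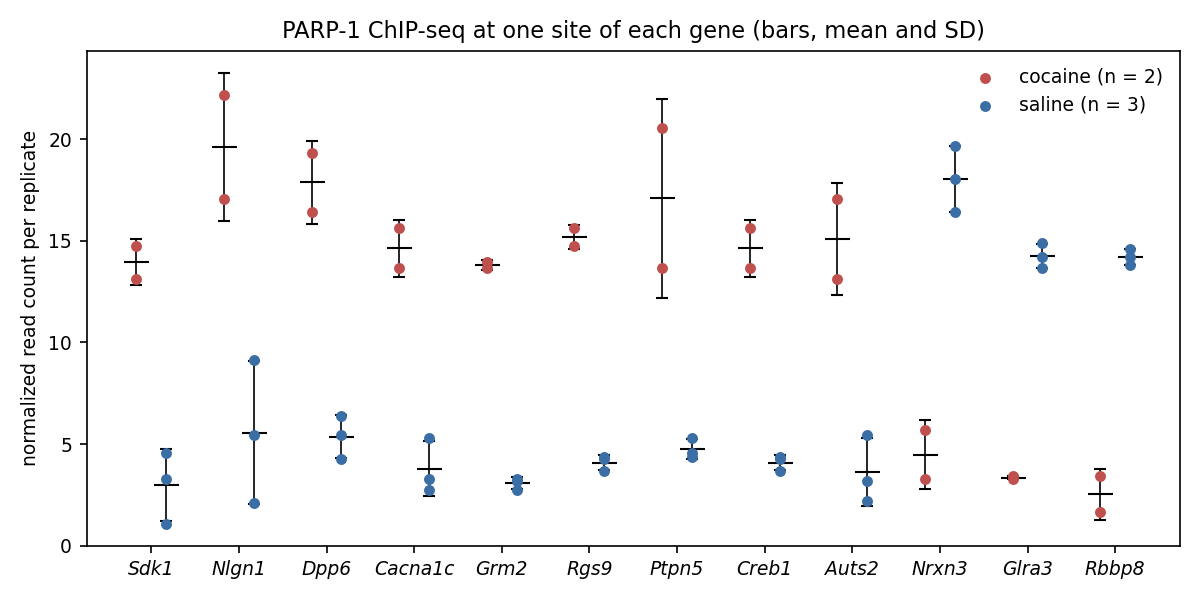
Normalized read count of each replicate (points) with mean and SD (bars) after cocaine (n = 2) and saline (n = 3) at one site of each of 12 genes named in the text. For Sdk1 the site at 142272701 is shown, at 14.0 normalized reads after cocaine and 2.97 after saline, and Nrxn3, Glra3 and Rbbp8 show the opposite direction.

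The lists of astrocyte, oligodendrocyte lineage and microglia and endothelial markers were short, matching 22, 28 and 33 gene symbols. The astrocyte list held 1 higher site, in Gli2, and the oligodendrocyte lineage list 1, in Bcas1, with log2 fold changes of 1.28 ± 0.35 and 1.92 ± 0.57 (SE). Each passed, also when adjusted over the list alone, and the microglia and endothelial list held 0 sites. No difference in the share of genes with a site was tested between lists. Chemosensory receptor genes, which form large families of similar copies, held 8 higher sites and 1 lower site in 8 genes. The promoter site of Olfr70 rose from 3.78 ± 1.36 to 17.0 ± 1.53 normalized reads. Other repeated gene families held 15 higher sites in 13 genes, among them Cyp2j6, Zfp541, Zfp236 and Zfp641. All 9 and all 15 passed, also when adjusted over each list alone, but reads from similar copies cannot be told apart from these values. Of the 14 lists, 0 differed between higher and lower genes (Fisher's exact test, two-sided, Benjamini-Hochberg over the lists). The smallest adjusted p was 0.726, with an unadjusted p of 0.0518, for the GABA, glycine and acetylcholine list. With 668 genes holding higher sites only and 18 lower sites only, this comparison had few lower genes.

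**Figure D3:**
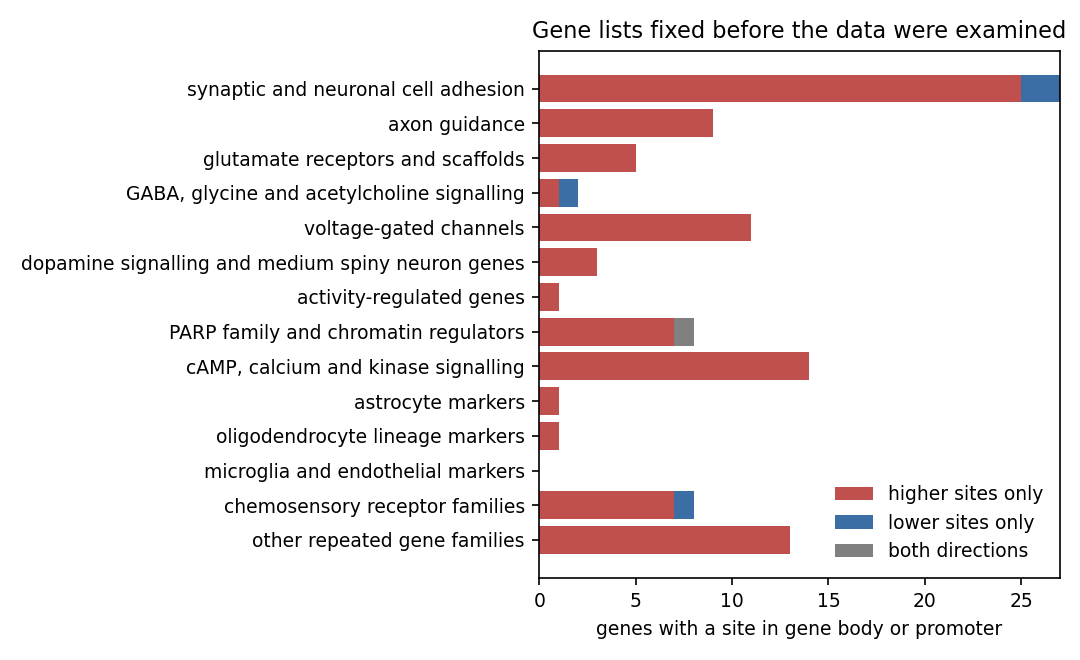
Number of genes of each list with a site in gene body or promoter (x axis), divided into genes with higher sites only, lower sites only and both directions. The adhesion list holds 27 such genes, and Macrod2 is the gene with both directions in the PARP and chromatin list.

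Among all genes, the largest increases named by the rule were at Mtap1a, the gene of a microtubule-associated protein, Pcsk6, the gene of a proprotein convertase, and Csf2rb, the gene of a cytokine receptor subunit. Mtap1a rose from 1.31 ± 1.15 to 13.4 ± 0.35 normalized reads (chromosome 2, 121131001 to 121132000), Pcsk6 from 1.58 ± 1.87 to 14.0 ± 1.15 (chromosome 7, 73134401 to 73135400) and Csf2rb from 1.73 ± 1.27 to 14.8 ± 0.01 (chromosome 15, 78164901 to 78166000). The RIKEN genes D630039A03Rik and 8430406I07Rik rose by 2.60 ± 0.41 and 2.49 ± 0.42 on the log2 scale. Slco3a1, an organic anion transporter gene, and Lingo1, the gene of a neuronal leucine-rich repeat protein, were among those with the smallest adjusted p in the authors' deposited table. Slco3a1 rose from 8.50 ± 2.29 to 31.1 ± 1.0 and Lingo1 from 9.44 ± 0.66 to 32.2 ± 2.12. Saline counts at such sites rested on few reads, for example 4 reads over the 3 saline replicates against 28 over the 2 cocaine replicates at Mtap1a. The lowest cocaine counts at higher sites with a mean count under 100 were 13.14 and 13.64 in the 2 replicates. The 13.4 ± 0.35 at Mtap1a, and at Ephb2 and Hmgb2, lay at this minimum. Of these 1567 higher sites, 848 (54.1%) lay within 1.1 times the minimum. Small SDs near it cannot be taken as a sign of close replicates.

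Lower sites in or near genes numbered 22. Rbbp8, which encodes a protein of DNA end resection, fell from 14.2 ± 0.40 to 2.52 ± 1.25 normalized reads, or by 2.15 on limma's log2 scale (SE 0.30; chromosome 18, 11895801 to 11896800). Thsd7b fell from 15.6 ± 1.84 to 3.19 ± 1.30, the adhesion receptor gene Gpr98 from 15.6 ± 1.24 to 3.19 ± 1.30 and Cadps2, a gene of dense-core vesicle release, from 15.5 ± 1.17 to 3.60 ± 1.88. Lrrc40 and Slco6c1 fell by 1.83 and 1.74 on the log2 scale (SE 0.23 and 0.26). Lrp1b, the gene of a lipoprotein receptor family member, held 2 lower sites, and its named one fell from 15.9 ± 0.44 to 4.17 ± 1.07. Gm13154 had higher counts than the rest, 43.9 ± 2.14 after saline and 18.2 ± 3.27 after cocaine. All of these passed limma's test.

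The gene with the most sites was Sfi1, which encodes a centrosome protein, with 20 higher sites between 3031301 and 3097700 on chromosome 11. Mean counts there reached 1391 normalized reads after cocaine, and the ratio of cocaine to saline ranged from 1.05 to 1.33 with a median of 1.15. None of the 20 passed limma's test, which gave 0 of 20, and the exact conditional p was under 1e-04 at 7. The authors' deposited table gave the named site (3054601 to 3055800) an adjusted p of 2.72e-07, with 432 ± 0.36 normalized reads after cocaine and 377 ± 3.75 after saline. limma's adjusted p was 0.423 and the exact conditional p was 0.00265. limma's log2 fold change there was 0.20 with an SE of 0.22, set largely by the sites of low count rather than by these replicates. Not passing limma's test therefore says little about small changes at sites of high count. The neighbouring Eif4enif1 site held 344 ± 1.45 against 330 ± 13.4 normalized reads and the Pisd-ps3 site 140 ± 9.55 against 100.6 ± 10.1, with limma adjusted p of 0.798 and 0.0979. Of the 69 sites with a mean count of 100 or more, 31 lay on chromosome Y and 23 at the start of chromosome 11, and 1 of the 69 passed limma's test.

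Higher sites lay more often in gene bodies and lower sites more often in gene deserts. A difference in pericentromeric sequence rested mostly on a stretch of chromosome Y. By the authors' annotation, 41.6% of the higher sites (667) and 14.8% of the lower sites (18) lay in gene bodies (Fisher's exact test, two-sided, adjusted p = 3.87e-09 over 7 classes). Gene deserts held 10.97% of the higher and 29.5% of the lower sites (adjusted p = 3.56e-07). Pericentromeric sequence held 0.81% and 18.03% (Fisher's exact test, adjusted p = 3.55e-17). Of its 22 lower sites, 18 lay in a single stretch of chromosome Y (2780201 to 2902800). The test counts such neighbouring sites as independent. Without the sites with a mean count of 100 or more, the pericentromere difference no longer passed (adjusted p = 0.122), while those of gene bodies (1.28e-04) and gene deserts (2.85e-09) did. Among sites with an authors' adjusted p under 0.001, the gene desert difference did not pass (adjusted p = 0.531). Promoter classes together held 81 higher and 4 lower sites and did not differ in share (adjusted p = 0.516). Among sites in or near genes, the median distance to the transcription start was 35.35 kb for 748 higher and 89.96 kb for 22 lower sites (two-sided permutation test, p = 0.0137). Restricted to sites with an adjusted p under 0.001, the difference did not pass (permutation p = 0.167).

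**Figure D4:**
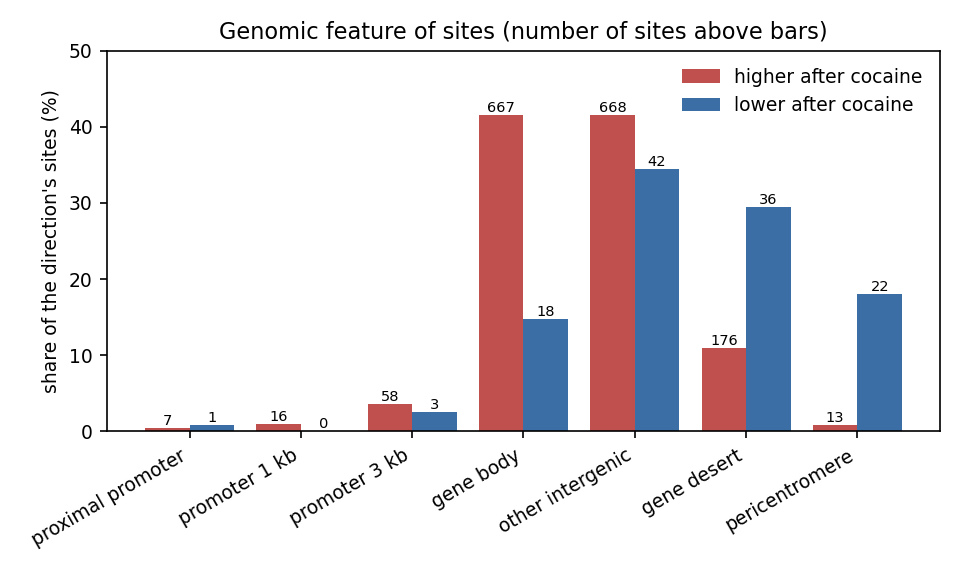
Share of the higher (red) and lower (blue) sites in each class of the authors' annotation (y axis, percent), with the number of sites above each bar. Gene bodies held 41.6% of the higher and 14.8% of the lower sites, and gene deserts 10.97% and 29.5%.

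Sites were spread over the autosomes, with 46 to 146 per chromosome, while chromosome X held 7 and chromosome Y 31. The balance of directions differed from the other chromosomes on chromosome Y (9 higher and 22 lower, Fisher's exact test, adjusted p = 1.83e-18), X (3 and 4, adjusted p = 0.00738) and 11 (113 and 1, adjusted p = 0.0259). Chromosome 11 did not pass at an authors' adjusted p under 0.01 (adjusted p = 0.0602) or with sites closer than 1 kb merged (0.0875), and X did not pass at an authors' adjusted p under 0.001 (0.0668). Of the 22 lower sites on chromosome Y, 18 lay in the stretch named above, so they were not independent. Without the sites with a mean count of 100 or more, 0 chromosomes passed (Fisher's exact test). Neighbouring sites within 100 kb had the same direction in 86.0% of 200 pairs, against 85.2% when directions were permuted within chromosomes (one-sided permutation test, p = 0.397). Without the sites with a mean count of 100 or more, the share was 93.8% of 146 pairs against 89.6% (permutation p = 0.0458), so the call changed with those sites.

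The authors' enrichment over background placed most higher sites above 1 after cocaine and below 1 after saline. In the authors' deposited table the median enrichment of the higher sites was 2.62 after cocaine and 0.79 after saline, and 72.6% of them exceeded 2 after cocaine against 6.18% after saline. At the lower sites the median was 1.43 after saline and 0.41 after cocaine, and 13.9% exceeded 2 after saline. The background used for these values was not given in the sources used here. At sites with a mean count under 100, the median count in the higher group was alike, 15.92 at higher and 15.94 at lower sites. The background implied by the authors' average and enrichment, computed after the values were seen, had medians of 6.15 and 11.6 there. The lower enrichment of the lower sites thus went with a higher background.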

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

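The limma and exact conditional counts, the leave-one-out values and the values without sites of mean count 100 or more were chosen after seeing the data. Under the settings that leave out a cocaine replicate, 52 of 150 values kept their side of the threshold or stayed within their spread, and 4 of 75 without cocaine replicate 2. Under the other settings that changed the data 469 of 499 did, and 0 of either reversed direction. The counts of sites and of genes, the feature classes, the gene lists and the median enrichment were kept with an adjusted p under 0.01 and with merging of sites closer than 1 kb. In both settings 2 chromosomes passed against 3, since chromosome 11 did not (Fisher's exact test, adjusted p = 0.0602 and 0.0875; range 0.0259 to 0.7998). A mean count of at least 10 in the higher group removed no site and so tested nothing. With an adjusted p under 0.001, which leaves fewer sites by construction, 375 higher and 33 lower sites remained, in 182 genes. Of these sites, 366 passed limma's test and 381 the exact conditional test. Their median log2 fold changes were 2.05 and -0.29, and the median cocaine enrichment of the higher sites was 2.94. At that threshold 1 chromosome passed, and the TSS distance differed by -56.5 kb without passing (permutation p = 0.167; range over the alternatives 0.0137 to 0.167). The share of higher sites was 94.5% with an absolute log2 fold change of at least 1, 94.3% on autosomes only and 94.5% without sites of mean count 100 or more. The median log2 fold change of the lower sites was then -2.04, -2.0 and -2.04, and 0 chromosomes passed in each. By permutation, the share of neighbours of the same direction passed at 93.7% (p = 0.0468), 94.1% (p = 0.0447) and 93.8% (p = 0.0458) in these settings and at 90.7% within 1 Mb (p = 9.00e-04), against 86.0% as planned. It did not pass at 75% within 10 kb (permutation p = 0.882), 84.2% with sites merged (0.607), 88.5% with an adjusted p under 0.01 (0.204) or 76.9% with one under 0.001 (0.948). The pericentromere difference did not pass with an absolute log2 fold change of at least 1 (Fisher's exact test, adjusted p = 0.0910; range 2.53e-17 to 0.122). The gene desert difference did not pass with an adjusted p under 0.001 (0.531; range 2.78e-09 to 0.531). The cause of these changes was not tested.

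Leaving out 1 replicate at a time gave 0 to 1651 sites past limma's threshold against 1649 with all. The low values came without cocaine replicate 1 (794) and without cocaine replicate 2 (0, with 1248 at an unadjusted p under 0.05). Each then left a single cocaine sample, assumed to vary like the saline samples, and the smallest adjusted p values were 0.0485 and 0.0561, so a small change in p moved the whole count. Of the 71 sites of named genes, 68 passed with all replicates, 44 without cocaine replicate 1 and 0 without cocaine replicate 2. The exact conditional test gave 215 to 587 sites against 1355, with 215 and 285 without cocaine replicates 1 and 2 and 556, 450 and 587 without saline replicates 1, 2 and 3. Fewer reads entered each of these by construction. The median log2 fold change ranged from 1.799 to 1.87 at higher sites and from -1.94 to -1.77 at lower sites. The direction turned at 0 to 2 of the 1727 sites. The authors' list itself could not be recalled without a replicate. No paired analysis was possible because the values carry no replicate numbers from the labels. Gene lists with intergenic sites within 50 kb gave no value, because 0 of the 957 sites outside genes carried a gene name, and the lists among all genes were not run for want of gene lengths in mm9. With medians of 3 to 5 reads per replicate in the lower group, depth limits the precision of each fold change.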

Other observations

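All tests in this part, and the genes and sites in the next paragraph except the Macrod2 sites starting at 141013001 and 142004401, which the rule for named genes gave, were chosen after the values were seen.

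Promoter classes held 85 sites in 85 genes, 81 higher and 4 lower after cocaine, and 82 passed limma's test. Within 1 kb of the start lay 23 higher sites and 1 lower site. Higher promoter sites included genes of vesicle release, Cplx2 (complexin-2; 3.85 ± 2.43 to 13.8 ± 0.23 normalized reads, SD, n = 3 and 2) and Doc2b (a calcium sensor; 4.11 ± 2.25 to 14.5 ± 1.96). The chromatin protein gene Hmgb2 rose from 1.98 ± 0.83 to 13.4 ± 0.35, on 6 against 28 reads. Nmnat1, which encodes a nuclear enzyme of the synthesis of NAD, the substrate of PARP-1, rose from 3.88 ± 3.16 to 14.5 ± 1.96 (limma adjusted p = 0.0215). From the start, the sites lay 2.3 kb downstream (Cplx2), 0.6 kb upstream (Doc2b), 1.0 kb upstream (Hmgb2) and 2.4 kb downstream (Nmnat1). With a single cocaine sample left, the log2 fold changes of these 4 sites were 1.71, 1.82, 2.34 and 2.02 without cocaine replicate 1. They were 1.74, 1.56, 2.29 and 1.76 without cocaine replicate 2, against 1.73, 1.69, 2.31 and 1.89 with all replicates. The genes with sites in both directions were 2, Macrod2 and Erbb4. In Macrod2, on chromosome 2, the sites starting at 141013001 and 142196501 fell to 3.50 ± 1.48 and 3.66 ± 2.86 from 14.5 ± 1.53 and 14.6 ± 0.74. Those starting at 141654301 and 142004401 rose to 19.7 ± 1.1 and 18.1 ± 0.08 from 6.90 ± 2.07 and 5.78 ± 0.67. In Erbb4, a neuregulin receptor gene, the site at 68262301 on chromosome 1 fell from 15.6 ± 1.84 to 3.76 ± 0.49 and that at 68589301 rose from 4.14 ± 1.30 to 15.8 ± 0.21.

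Most listed sites were higher after cocaine. A scaling of the cocaine libraries large enough to give the whole change is argued against. The sites with a mean count of 100 or more had a median log2 fold change of 0.04, against 1.83 at the others. A smaller scaling error stays open. Among sites with a mean count of 100 or more, the median was -0.06 in a stretch of 26 on chromosome Y and 0.20 in one of 23 on chromosome 11. A minimum read count is visible in the table, since no replicate of the higher group held fewer than 12 reads at sites with a mean count under 100, and 2 cocaine replicates may meet it more easily than 3 saline replicates. This minimum stays open. For the next split it was set at 14.19 normalized reads, the lowest count of saline replicate 3 there. Where the higher group's mean was at least 2 times that value, 62.2% of 90 sites were higher (exact 95% interval 51.4 to 72.2%). This was 85.7% of the 21 with a mean count under 100 (63.7 to 97.0%) and 55.1% of the 69 others (42.6 to 67.1%), so the parts did not decide it. Of the 69, 1 passed limma's test and 19 had an exact conditional p under 1e-04. limma's spread is shared with sites of low count, so their small changes could hardly pass and its result does not weigh them. With the minimum for every replicate raised 1.2-fold and 1.5-fold, 95.9% and 92.3% of sites with a mean count under 100 were higher. Their intervals were 93.5 to 97.6% and 84.0 to 97.1%. A raised minimum must again be met by 2 or by 3 replicates, so this did not decide it. For the 1637 sites nearer the minimum, 94.6% higher, its effect cannot be told apart from an effect of cocaine, because sites under the minimum were not listed and cocaine itself stays untested beyond this comparison.

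Sites with a mean count of 100 or more had small p-values with small changes in the authors' deposited table. Of the 52 such sites with an authors' p under 1e-04, 34.6% also had an exact conditional p under 1e-04 (exact 95% interval 22.0 to 49.1%), against 84.9% of the 1552 other sites. Counting error alone is the least spread that replicates can have, so the values are consistent with p-values at high counts that the reads do not bear out. At 18 of the 69 sites the replicate ranges of cocaine and saline overlapped. At one of them, on chromosome Y at 2881101 to 2882100, the counts were 326 ± 6.70 after cocaine and 337 ± 18.3 after saline, with p = 4.76e-11 in the authors' deposited table and an exact conditional p of 0.569. Whether reads of several repeat copies were gathered at these sites was not tested, since no genome sequence was at hand.

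Chromosome X held 7 sites against 46 or more on each autosome. The lowest mean count of an X site was 56.1, above 97.9% of the 1689 autosomal sites, whose median was 9.24. A chromosome at lower copy number that rarely reached the minimum read count would give this, but the value cannot decide it. It restates the lack of low-count sites on X, since 5 of the 7 X sites had a mean count of 100 or more. The labels give no sex of the mice. A difference of PARP-1 occupancy on X was not tested.

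The background implied by the authors' average and enrichment had a median of 6.15 normalized reads at higher and 11.6 at lower sites with a mean count under 100 (two-sided permutation test, p = 1e-05, the smallest that 100000 resamples give).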
